A study of Homo sapiens with 87 samples.

How the data were processed

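Total RNA of 87 human scalp biopsies was sequenced on an Illumina instrument. Per the labels, biopsies were fixed with PAXgene, RNA was taken with RNeasy Mini columns, and the controls came from healthy volunteers of other studies. The groups, as the labels give them, were FFA (36 libraries), LPP (30), CCCA (9) and NC (12). Per the authors' notes, reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.5.2b and counted with featureCounts of Subread 1.5.2 on GRCh38, and DESeq2 was used for comparisons.

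The deposited files were of 3 kinds. Each of 21 libraries (6 FFA, 3 LPP and 12 NC) had a table in which the authors gave raw counts, gene length and FPKM for 25559 genes. Rebuilding FPKM from the counts and lengths matched the deposited FPKM within 0.005. The authors deposited featureCounts tables of raw counts for the other 66 libraries, with 57500 features in title series 0 and 55782 in series 2. Per the file headers, the authors' 3 comparison tables held log2 fold changes with standard errors, raw and adjusted p-values, a test statistic, and a mean normalized count, which is a score per gene. That mean was the same in all 3 tables, so they came from 1 joint fit, and which libraries and covariates entered it is not known. The tables had 32822 rows, 8442 of them without a symbol.

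The 2 series of count libraries were joined on 55535 features with identical exons, which held from 98.23% to 99.71% of each library's counts. Genes on chromosome Y, XIST and TSIX were left out of every test and table, 115 features in the FPKM libraries, 512 in the count libraries and 225 rows of the authors' tables. Depth was the total count per library, from 14372085 to 27705003 in the FPKM libraries, 11736004 to 29671133 in series 0 and 11894490 to 27495456 in series 2. The 10 genes with most counts took 4.29% to 7.44% of an FPKM library, 7.80% to 15.0% of a series 0 library and 8.54% to 17.1% of a series 2 library. No pair of libraries was identical. A chi-square per gene between libraries of 1 group and series, over genes with a summed count of at least 20, was never under 9.61 in 84 pairs of FPKM libraries and 18.1 in 410 pairs of count libraries, far above sampling noise.

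Samples were compared only within a kind of file. FFA with NC, LPP with NC and FFA with LPP were tested in the 21 FPKM libraries, and FFA with LPP, CCCA with FFA and CCCA with LPP in the 66 count libraries. Each set was fitted once with all 3 of its groups, using edgeR 4.0.16 (TMM factors, robust quasi-likelihood test, two-sided) under R 4.3.3, with title series as a covariate in the count libraries. The filterByExpr function of edgeR left 17756 genes in the FPKM libraries and 23343 in the count libraries. In the FPKM libraries, no covariate could be used because patients and controls had separate title ranges. The Benjamini-Hochberg adjustment ran over all genes tested in a comparison, with a threshold of 0.05. For the FPKM libraries, limma 3.58.1 on log2(FPKM + 1) with a trend had been chosen before the data were examined. Because the files turned out to hold raw counts, the edgeR test, planned as its alternative, was made the main one and the limma test kept as an alternative. The limma test used genes with FPKM of at least 1 in at least 3 libraries, which left 15483. Group levels are mean FPKM or counts per 1e6 counts of the library (CPM) with SD.

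Before the data were examined, 37 gene lists were fixed for pathways, cell types of skin and scalp, and signs of RNA and library quality. They were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. In the FPKM libraries, where 36 of them could be tested, the mean log2(FPKM + 1) of each list's members was also compared by an exact two-sided permutation test over all regroupings, 18564 for FFA with NC, 455 for LPP with NC and 84 for FFA with LPP. The smallest p this test could give for LPP with NC was 0.0022, and the 84 regroupings of FFA with LPP could not call a lone list after adjustment over the lists. In the count libraries, list scores (mean log2 CPM with a prior count of 1) of FFA and LPP were compared by 100000 permutations within series, chosen after seeing the data. Counts of list members are given over all genes tested and adjusted over the list alone.

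Genes were named by a rule fixed before the data were examined. It took, per comparison, up to 5 genes in each direction with the largest absolute log2 fold change among calls with a mean of at least FPKM or CPM 5 in the higher group and a gene symbol that is not a clone name. It added up to 4 members with the smallest p from each list described. It also added 12 genes in every comparison, CXCL9, CXCL10, GZMB, CD8A, TPSAB1, KIT, COL1A1, PPARG, HMGCS1, KRT15, KRT85 and CYP1B1. Immunoglobulin and T cell receptor segments and the HLA-DR beta and HLA-DQ genes, whose copies differ between people, were tested but not named. Single members named for a small count of calls or a sign against their list, such as CDH2, KRT82, CD27, RPL13, MT-ND6 and HSPA1B, were chosen after their values were seen. Some genes that met these rules are not reported here. Gene positions were taken from the deposited count tables (GRCh38).

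The similarity of FFA and LPP fold changes against shared controls was set beside 20 simulations of unchanged groups and 20 splits of the controls into groups of 6. CCCA was set against NC by adding the CCCA with FFA fold change of the count libraries to the FFA with NC fold change of the FPKM libraries, or by the same route through LPP, with standard errors added in quadrature and no p. The authors' tables were summarised at cut-offs chosen for the summary, an adjusted p, as the authors gave it, under 0.05 and an absolute log2 fold change of at least 1.

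The tests were tested on simulated data, with 200 changed genes placed in unchanged groups of the same sizes. At a 2-fold change edgeR recovered 83.6% (FFA with NC), 64.2% (LPP with NC) and 67.2% (FFA with LPP) of the genes in the FPKM libraries, with 7, 7 and 5 false calls. It recovered 92.5% (FFA with LPP), 82.1% (CCCA with FFA) and 76.1% (CCCA with LPP) in the count libraries, with 7, 4 and 6 false calls. A list moved 2-fold passed, and 0 of 35 other lists did. The simulated genes were drawn independently of each other. This simulation therefore cannot show how often the list test calls falsely when list members are correlated, as in the real libraries.

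The alternatives set beforehand were limma on log2(FPKM + 1), with a pseudocount of 0.1, without a filter, on TPM and on quantile-normalized values, edgeR without a filter, and a fit on the 2 groups compared. For the count libraries they were DESeq2's size factors in edgeR, DESeq2 1.42.0, limma-voom, no filter, no series covariate and each series alone. Each LPP replicate of the FPKM libraries was left out in turn. Chosen after seeing the data were DESeq2 and its size factors in the FPKM libraries, removal of a length trend (span 0.3) from each library, leaving out each FFA replicate of the FPKM libraries and each CCCA replicate, limma fold changes of log2(FPKM + 1) for the similarity of FFA and LPP, and the T cell score as a covariate. Tables were handled with version 1.17.8 of data.table, pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and figures drawn with matplotlib 3.10.9.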

Results

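RNA from human scalp biopsies was sequenced in 87 libraries. They came from frontal fibrosing alopecia (FFA, 36 libraries), lichen planopilaris (LPP, 30), central centrifugal cicatricial alopecia (CCCA, 9) and normal controls (NC, 12). These 3 diseases are primary cicatricial alopecias, in which inflamed hair follicles are lost to scar tissue. The 21 FPKM libraries (6 FFA, 3 LPP and 12 NC) had total counts of 14372085 to 27705003, with a median of 20946821. The 66 count libraries carried titles of 2 series. Series 0 held 12 FFA, 13 LPP and 7 CCCA libraries with 11736004 to 29671133 counts (median 17825456). Series 2 held 18 FFA, 14 LPP and 2 CCCA libraries with 11894490 to 27495456 counts (median 16576405). Every control was an FPKM library and every CCCA library a count library, so diseases were set against controls only among the FPKM libraries. There, the title numbers of patients and controls formed separate ranges, so disease and any batch that follows the titles cannot be told apart. The labels gave neither donor nor lesional status per library, so p-values measure the spread between libraries, some of which may share a donor. Group values below are means ± SD, and log2 fold changes are given ± standard error.

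The comparison of FFA with NC asked which transcripts differ between diseased and normal scalp. In FFA (n = 6), sebaceous gland, cholesterol synthesis and peroxisome genes were lower than in NC (n = 12). Mast cell, fibrillar matrix and adipocyte genes were higher. Of 17756 genes tested with edgeR, 3677 rose and 3117 fell at the adjusted p threshold of 0.05, and 8317 passed it unadjusted. Other settings moved this balance. It was 3356 higher and 3354 lower by edgeR without a filter. By limma on log2(FPKM + 1) it was 4147 and 2051, with 4090 and 2060 at a pseudocount of 0.1. Limma without its filter gave 4652 and 2121, on TPM 3383 and 2275, and after quantile normalization 2929 and 3011. Of the called genes, 1036 rose and 499 fell by at least 1 on the log2 scale. Among 17 sebaceous gland genes, 16 fell, and 16 adjusted over the list alone, with a median log2 fold change of -2.64 (adjusted p = 0.541 with an estimated correlation). Fatty acid synthase, FASN (ENSG00000169710, chromosome 17, 82078333 to 82098332), fell by 6.25-fold, from 220.9 ± 67.6 to 37.2 ± 29.9 FPKM. The wax ester synthase AWAT1 (-3.39 ± 0.90, 7.63 ± 9.56 against 75.4 ± 38.6 FPKM), the lipoxygenase ALOX15B (-3.38 ± 0.72, 34.7 ± 39.2 against 344 ± 134 FPKM), KRT79 (-2.34 ± 0.41) and the melanocortin receptor MC5R (-3.13 ± 0.59) also fell. Among 22 cholesterol synthesis genes, 21 fell, and 21 adjusted over the list alone, with a median of -1.27 (adjusted p = 0.541 with an estimated correlation). They included DHCR7, which makes cholesterol from 7-dehydrocholesterol (ENSG00000172893, chromosome 11, 71428193 to 71452868, -1.67 ± 0.27, 46.4 ± 24.1 against 139 ± 31.4 FPKM), NSDHL (-1.55 ± 0.24), CYP51A1 (-1.07 ± 0.18) and HMGCS1 (-1.94 ± 0.42, 105 ± 79.8 against 382 ± 173 FPKM). Among 16 peroxisome genes, 11 fell, PECR (-2.21 ± 0.40) and PEX3 (-1.21 ± 0.18) among them, and 1 rose, with the same counts adjusted over the list alone (adjusted p = 0.541 with an estimated correlation). Of 15 mast cell genes, 14 rose, and 14 adjusted over the list alone, with a median of 1.68 (adjusted p = 0.541 with an estimated correlation). Chymase, CMA1 (ENSG00000092009, chromosome 14, 24505353 to 24508265), rose 6.45-fold (29.2 ± 17.1 against 4.19 ± 1.29 FPKM), with HDC, which makes histamine (2.28 ± 0.33), CTSG (1.73 ± 0.21), tryptase TPSAB1 (1.52 ± 0.22, 60.6 ± 15.5 against 19.7 ± 6.56 FPKM) and the stem cell factor receptor KIT (0.80 ± 0.20, 17.8 ± 6.93 against 9.49 ± 2.64 FPKM). Mean list scores put 6 of 6 FFA libraries above every control for mast cell genes, and 4 of 6 below every control for sebaceous genes (exact permutation test of scores, two-sided, adjusted p = 0.00129 and 0.00129).

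Matrix, fat and vessel genes also differed between FFA and NC. Of 25 fibrillar matrix genes, 19 rose and 0 fell, and 20 rose and 1 fell adjusted over the list alone (median 0.98, adjusted p = 0.571 with an estimated correlation). Examples were COL12A1 (1.35 ± 0.16, 29.6 ± 6.35 against 10.9 ± 3.46 FPKM), CTHRC1 (1.42 ± 0.19), fibrillin FBN1 (1.63 ± 0.25) and collagen COL1A1 (1.16 ± 0.27, 240.1 ± 70.9 against 100.4 ± 41.2 FPKM). Of 12 adipocyte genes, 9 rose, with complement factor D, CFD (1.32 ± 0.17, 269 ± 56.2 against 101 ± 25.9 FPKM), CIDEC (2.02 ± 0.35) and leptin, LEP (2.53 ± 0.44), whereas CIDEA fell (-1.82 ± 0.34), as did the lipid regulator PPARG (-0.65 ± 0.23, 8.74 ± 2.90 against 12.9 ± 3.99 FPKM). The adipocyte counts were the same adjusted over the list alone (adjusted p = 0.571 with an estimated correlation). Of 12 endothelial genes, 4 rose, and 8 adjusted over the list alone (adjusted p = 0.706 with an estimated correlation), among them the tight junction gene CLDN5 (1.34 ± 0.16), EGFL7 (0.93 ± 0.15) and PECAM1 (0.78 ± 0.16). Of 12 mesenchymal transition genes, 9 rose, S100A4 (1.30 ± 0.18) and PDGFRB (1.05 ± 0.20) among them, and CDH2 fell, with the same counts adjusted over the list alone (adjusted p = 0.706 with an estimated correlation). The hemoglobin gene HBB rose (2.30 ± 0.65, 221.3 ± 92.7 against 42.1 ± 48.9 FPKM), as 1 of 3 red blood cell genes did, and 1 adjusted over the list alone. Of 11 eccrine gland genes, 4 fell, and 4 adjusted over the list alone, PIP (-2.997 ± 0.67) and DCD (-2.12 ± 0.61) among them. Hair shaft keratins gave 1 call in 15, KRT82, and 0 adjusted over the list alone, and KRT85 stood at -0.32 ± 0.43 (744 ± 598 against 884 ± 401 FPKM, edgeR adjusted p = 0.578). Of 13 hair follicle stem cell genes, 4 fell and 2 rose, and 5 fell and 2 rose adjusted over the list alone. Among them were SOX9 (-0.996 ± 0.15), LHX2 (-0.89 ± 0.22) and the thyroid hormone deiodinase DIO2 (0.95 ± 0.14), and the follicle keratin KRT15 fell (-0.63 ± 0.21, 513 ± 92.9 against 741 ± 291 FPKM). The root sheath gene TCHH (-1.01 ± 0.26), the stimulus response genes EGR2 (-0.96 ± 0.16) and EGR3 (-0.997 ± 0.16), and CYP1B1, a target of the aryl hydrocarbon receptor (-0.49 ± 0.14, 23.5 ± 5.10 against 31.01 ± 6.54 FPKM), fell as well. EGR2 and EGR3 belong to the immediate early and heat shock list, a sign of sample handling, of which 7 of 15 genes fell. Outside the lists, ZBED6 (4.70 ± 0.30), KRTAP20-1 (3.85 ± 0.96), KRTAP20-2 (3.16 ± 0.76) and PLA2G2A (3.08 ± 0.46) rose, and PDE6A (-3.93 ± 0.87), FABP7 (-3.66 ± 0.77) and MUC1 (-3.28 ± 0.60) fell. Calls ended for PPARG without FFA replicates 2 or 3 (to -0.57), for KRT15 without replicate 5 (to -0.56) and for KRTAP20-2 without replicate 1 (to 1.69). KRTAP20-1 was called in 4 of the 6 fits without 1 FFA replicate (4.02 to 4.09). In the others it did not pass the filter on low counts and was not tested, so its rise rests on few libraries. The calls of PPARG and KRT15 also ended with limma on log2(FPKM + 1).

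Interferon induced, cytotoxic and macrophage genes were also higher in FFA than in NC. Of 18 interferon gamma induced genes, 15 rose, and 15 adjusted over the list alone, with a median log2 fold change of 0.95 (exact permutation adjusted p = 0.0146, adjusted p = 0.738 with an estimated correlation). The list score was above the NC median in only 4 of 6 FFA libraries, against 6 for the type I interferon list and 5 each for the cytotoxic and macrophage lists. The chemokine CXCL10, which draws T cells, rose 9.93-fold (ENSG00000169245, chromosome 4, 76021117 to 76023497, 11.6 ± 11.2 against 1.07 ± 0.825 FPKM). CXCL9 (2.59 ± 0.80, 10.97 ± 12.4 against 1.69 ± 1.65 FPKM), IRF1 (1.12 ± 0.25) and PSMB8 (0.90 ± 0.18) rose too. Of 21 type I interferon induced genes, 16 rose, and 16 adjusted over the list alone, IFI44 (1.84 ± 0.25) and IFI44L (1.83 ± 0.28) among them (adjusted p = 0.706 with an estimated correlation). Of 15 cytotoxic lymphocyte genes, 10 rose, and 10 adjusted over the list alone (adjusted p = 0.842 with an estimated correlation). NKG7 (1.86 ± 0.46), the granzymes GZMH (2.08 ± 0.57) and GZMB (1.76 ± 0.49, 1.38 ± 0.971 against 0.376 ± 0.3203 FPKM) and CD8A (1.42 ± 0.50, 1.95 ± 1.71 against 0.672 ± 0.492 FPKM) were among them. Of 15 macrophage genes, 9 rose, and 10 adjusted over the list alone, with STAB1 (1.66 ± 0.23) and TYROBP (0.99 ± 0.22) among them (adjusted p = 0.755 with an estimated correlation). The T cell list gave 2 calls in 15, CD27 among them, and 1 adjusted over the list alone. CCR7 (1.72 ± 0.38) and IL1RL1, the interleukin-33 receptor also carried by mast cells (3.001 ± 0.31, 1.22 ± 0.474 against 0.141 ± 0.0729 FPKM), rose. Leaving out 1 FFA library ended the call of CXCL9 (replicate 4, to 1.89), GZMH (replicate 3, to 1.28) and CD8A (replicates 3, 4 and 6, down to 0.90). CXCL9 also lost its call with limma on log2(FPKM + 1), and CD8A with quantile normalization.

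**Figure D1:**
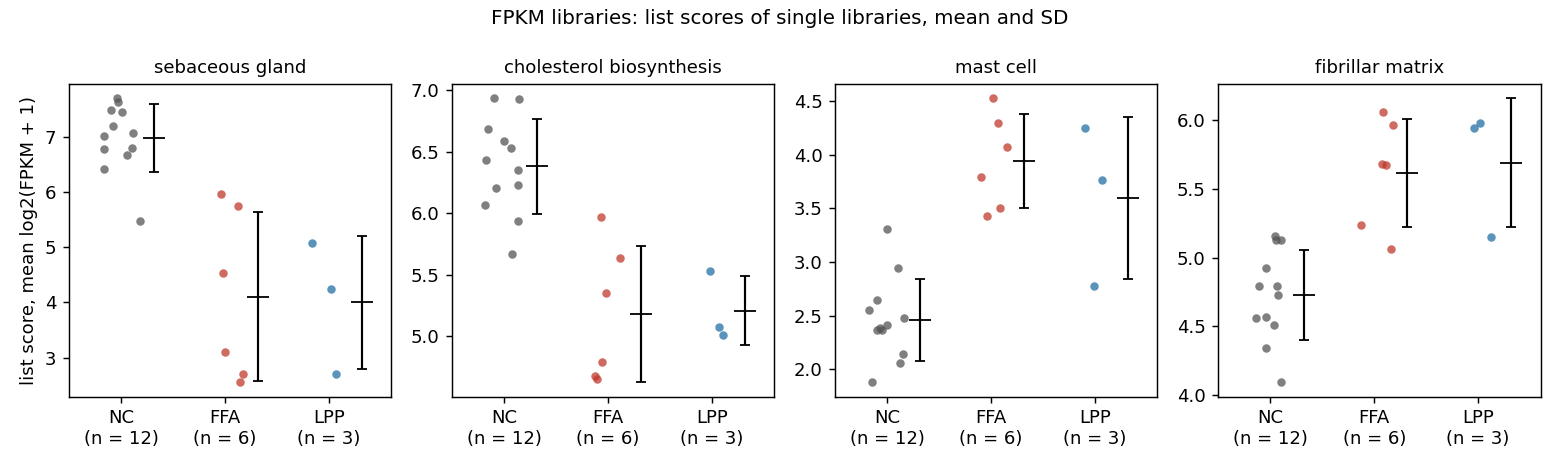
Mean log2(FPKM + 1) of the sebaceous gland, cholesterol biosynthesis, mast cell and fibrillar matrix lists in the 21 FPKM libraries. Each point is a library of NC (n = 12), FFA (n = 6) or LPP (n = 3), and bars show the mean ± SD. Mast cell scores reached from 3.43 to 4.53 in FFA and from 1.88 to 3.31 in NC, and sebaceous gland scores from 2.55 to 5.96 in FFA and from 5.48 to 7.71 in NC.

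The comparison of LPP with NC asked the same of lichen planopilaris, with 3 LPP libraries. As in FFA, sebaceous gland and cholesterol synthesis genes were lower and mast cell and matrix genes higher, and epidermal stress genes were higher as well. edgeR called 2625 genes higher and 2074 lower of 17756, with 6796 past the threshold unadjusted, and 1022 rose and 500 fell by at least 1 on the log2 scale. The balance turned to 2252 higher and 2269 lower with edgeR without a filter, 1556 and 1985 with limma on TPM and 1948 and 2102 with limma after quantile normalization. It was 2532 and 1585 with limma on log2(FPKM + 1). Of 22 cholesterol synthesis genes, 19 fell, and 20 adjusted over the list alone, with a median of -1.23 (adjusted p = 0.653 with an estimated correlation). NSDHL (-1.48 ± 0.32), DHCR7 (-1.66 ± 0.37) and HMGCS1 (-2.11 ± 0.57, 91.1 ± 25.5 against 382 ± 173 FPKM) were among them. Of 17 sebaceous gland genes, 12 fell, and 16 adjusted over the list alone, with a median of -2.998 (adjusted p = 0.653 with an estimated correlation). FAR2, which makes the alcohols of wax (ENSG00000064763, chromosome 12, 29149103 to 29340980), fell 16.96-fold (6.89 ± 5.62 against 116 ± 59.4 FPKM), with FASN (-2.92 ± 0.61), KRT79 (-2.54 ± 0.57) and AWAT1 (-4.48 ± 1.34). Peroxisome genes gave 6 lower and 1 higher of 16, and 8 lower and 1 higher adjusted over the list alone, with PEX3 (-1.15 ± 0.24) and PECR (-2.48 ± 0.55) lower (adjusted p = 0.653 with an estimated correlation). Of 15 mast cell genes, 12 rose, and 14 adjusted over the list alone (median 1.48, adjusted p = 0.653 with an estimated correlation), among them TPSB2 (1.76 ± 0.30), CMA1 (1.89 ± 0.33), TPSAB1 (1.48 ± 0.27, 58.4 ± 30.5 against 19.7 ± 6.56 FPKM) and KIT (0.83 ± 0.25). Of 25 fibrillar matrix genes, 18 rose, and 19 adjusted over the list alone (median 1.10, adjusted p = 0.653 with an estimated correlation), with COL12A1 (1.63 ± 0.20), CTHRC1 (1.501 ± 0.23), FBN1 (1.76 ± 0.30) and COL1A1 (1.28 ± 0.33, 250.4 ± 122 against 100.4 ± 41.2 FPKM). Without LPP replicates 1 and 3 in turn, 3132 and 2902 genes were called, and HMGCS1 and AWAT1 lost their calls (AWAT1 to as little as -3.95, HMGCS1 to -1.96). COL1A1 lost its call without replicates 2 or 3 (down to 0.94) and KIT without replicate 3 (0.42).

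Some epidermal stress and interferon induced genes were also higher in LPP than in NC. Of 21 epidermal stress and antimicrobial genes, 12 rose above NC, and 13 adjusted over the list alone, with a median log2 fold change of 2.15 (exact permutation adjusted p = 0.0622, adjusted p = 0.708 with an estimated correlation). They included S100A12 (4.65 ± 0.63, 16.6 ± 16.5 against 0.618 ± 0.586 FPKM), the elastase inhibitor PI3 (4.06 ± 0.83, 1047 ± 1283 against 59.6 ± 48.2 FPKM), the defensin DEFB4A (4.07 ± 0.95) and S100A7 (2.58 ± 0.60). Outside this list, IGFL1 (5.71 ± 0.75), ZBED6 (4.80 ± 0.33), TCN1 (4.48 ± 0.73) and S100A7A (4.44 ± 0.83) rose, and HGD (-4.08 ± 0.78), OLAH (-4.29 ± 1.19) and SEC14L6 (-4.47 ± 1.36) fell. Type I interferon induced genes gave 11 calls in 21, and 11 adjusted over the list alone, with OASL (1.99 ± 0.33) and IFIT2 (0.99 ± 0.22) higher (adjusted p = 0.653 with an estimated correlation). Interferon gamma induced genes gave 3 calls in 18, GBP5 (1.65 ± 0.59) and PSMB8 (0.87 ± 0.23) among them, and 2 adjusted over the list alone (adjusted p = 0.749 with an estimated correlation). CXCL9 stood at 0.87 ± 1.03 (3.29 ± 2.67 against 1.69 ± 1.65 FPKM) and CXCL10 at 1.14 ± 0.86 (2.53 ± 2.05 against 1.07 ± 0.825 FPKM), short of the threshold (edgeR adjusted p = 0.563 and 0.349). Cytotoxic genes gave 5 calls in 15, CST7 (1.28 ± 0.37) and NKG7 (1.74 ± 0.56) among them, and 6 adjusted over the list alone (adjusted p = 0.708 with an estimated correlation), while GZMB (1.38 ± 0.61) and CD8A (1.29 ± 0.62) missed the threshold. PPARG (-0.76 ± 0.31), KRT15 (-0.18 ± 0.26), KRT85 (-0.55 ± 0.56) and CYP1B1 (-0.48 ± 0.18) missed it too. Leptin (2.48 ± 0.51) and CFD (1.37 ± 0.21) rose with 7 of 12 adipocyte genes, and 9 adjusted over the list alone (adjusted p = 0.656 with an estimated correlation), MMP2 (1.78 ± 0.31) with 7 of 12 mesenchymal transition genes, and 8 adjusted over the list alone (adjusted p = 0.653 with an estimated correlation). CLDN5 (1.53 ± 0.20) rose with 6 of 12 endothelial genes, and 8 adjusted over the list alone (adjusted p = 0.653 with an estimated correlation), and HBB (3.51 ± 0.75) with 3 of 3 red blood cell genes, and 3 adjusted over the list alone (adjusted p = 0.653 with an estimated correlation). STAB1 (1.85 ± 0.28) and DIO2 (1.31 ± 0.18) rose, and SOX9 (-1.30 ± 0.20), PIP (-3.17 ± 0.92) and DCD (-2.89 ± 0.87) fell. Without LPP replicate 1 the calls of PI3 (2.37), DEFB4A (3.04), S100A7 (1.36), S100A7A (2.52) and PSMB8 (0.50) ended. Without replicates 1 or 3 those of CST7 (down to 0.94), NKG7 (to 1.01, and with limma on log2(FPKM + 1)), PIP (to -2.86), DCD (to -2.49), OLAH (to -3.80) and SEC14L6 (to -3.97) ended, as did GBP5 without any 1 of the 3 (to 1.37) and LEP without replicate 3 (to 1.52).

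FFA and LPP were compared with each other in the FPKM libraries to ask which transcripts tell the diseases apart. The epidermal stress list had the largest median difference, -2.72, with lower values in FFA, and none of its 21 members passed over all genes while 13 passed adjusted over the list alone. The camera adjusted p was 4.76e-21, lost with an estimated correlation (adjusted p = 0.196 with an estimated correlation). S100A12 (-3.85 ± 0.75, 1.15 ± 0.591 against 16.6 ± 16.5 FPKM), S100A7 (-2.86 ± 0.73), S100A9 (-3.14 ± 0.84) and SPRR2B (-3.26 ± 0.87) had the smallest p of that list, with edgeR adjusted p from 0.156 to 0.492. In all, edgeR called 0 of 17756 genes, with 806 past the threshold unadjusted, while limma on log2(FPKM + 1) called 2 and DESeq2 16. Without LPP replicate 3, edgeR called 24 genes, S100A12 among them (to -4.38). The interferon gamma list gave a median of 0.22 with 0 calls, and CXCL9 (1.72 ± 1.26), CXCL10 (2.18 ± 1.05) and CXCL11 (2.44 ± 1.01) were higher in FFA by less than 3 standard errors. GZMB (0.37 ± 0.68), CD8A (0.12 ± 0.72), TPSAB1 (0.04 ± 0.32), KIT (-0.03 ± 0.29), COL1A1 (-0.12 ± 0.39), PPARG (0.10 ± 0.32), HMGCS1 (0.17 ± 0.54), KRT15 (-0.45 ± 0.28), KRT85 (0.22 ± 0.60) and CYP1B1 (-0.01 ± 0.20) did not pass. Genes that moved in FFA against NC tended to move the same way in LPP against NC. Both diseases shared 2235 higher and 1789 lower calls, where independent lists would share 543.6 and 364.08, and 1 gene was called in opposite directions. The 2 sets of fold changes correlated across genes, which are not independent replicates, with Pearson r = 0.844 and Spearman rho = 0.834. The shared controls alone gave a mean r of 0.259 in 20 simulations of unchanged groups, and r averaged 0.776 when each disease had its own 6 controls. The covariance was 0.395, against 0.0220 in the simulations. A batch that follows the titles would move both diseases the same way against the controls, and none of these values tests it.

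The count libraries put the same question to more biopsies, 30 FFA and 27 LPP. Interferon gamma induced genes were higher in FFA, and cytotoxic and antigen presentation genes with them. Of 18 interferon gamma induced genes, 9 rose over all genes and 18 adjusted over the list alone, with a median log2 fold change of 0.89, and 27 of 30 FFA libraries scored above the LPP median. This list held with an estimated correlation (adjusted p = 0.00415 with an estimated correlation) and in a permutation test of scores within series (adjusted p = 0.00444). The immediate early and heat shock list, a sign of sample handling, had a median of 0.35 with 0 calls in 15, and 0 adjusted over the list alone. Its camera adjusted p was 7.38e-05 (adjusted p = 0.396 with an estimated correlation), and its median 0.04 in series 0 and 0.64 in series 2. The chemokine CXCL9 (ENSG00000138755, chromosome 4, 76001275 to 76007488) rose 6.26-fold (2.65 ± 0.55, 50.1 ± 68.6 against 10.5 ± 18.9 CPM), with CXCL10 (2.36 ± 0.53, 19.8 ± 27.7 against 4.79 ± 9.04 CPM), CXCL11 (2.37 ± 0.49), the guanylate-binding genes GBP4 (0.92 ± 0.20) and GBP5 (1.36 ± 0.30), IRF1 (0.89 ± 0.17, 64.05 ± 38.1 against 34.5 ± 15.8 CPM) and the peptide transporter TAP1 (0.61 ± 0.13). Of 17 cytotoxic lymphocyte genes, 1 rose, GZMH (1.58 ± 0.33), and 16 adjusted over the list alone, with a median of 0.88 (adjusted p = 0.0178 with an estimated correlation). CD8A (1.09 ± 0.26, 10.8 ± 9.64 against 5.03 ± 4.01 CPM) and GZMB (1.13 ± 0.30, 2.30 ± 2.15 against 1.05 ± 0.874 CPM) had edgeR adjusted p = 0.0710 and 0.123. Of 15 antigen presentation genes, 1 rose, HLA-F (0.76 ± 0.17), and 14 adjusted over the list alone (median 0.44, adjusted p = 0.0178 with an estimated correlation). No T cell gene of 15 passed over all genes and 12 passed adjusted over the list alone, with a median of 0.74 (adjusted p = 0.105 with an estimated correlation), ICOS at 1.33 ± 0.36 and CD2 at 0.90 ± 0.26. edgeR called 25 of 23343 genes in all, 21 higher and 4 lower in FFA, and 1435 passed unadjusted. The secretory gene SYT8 (1.41 ± 0.30, 18.9 ± 19.1 against 6.79 ± 4.62 CPM) was among the higher ones, and the 4 lower ones were 3 immunoglobulin segments and the transcription factor ZIC1 (-0.63 ± 0.13). Mast cell, matrix, lipid and hair genes did not pass, with TPSAB1 at -0.06 ± 0.18, KIT at 0.00 ± 0.15, COL1A1 at -0.29 ± 0.24, PPARG at 0.03 ± 0.15, HMGCS1 at -0.02 ± 0.26, KRT15 at 0.06 ± 0.12, KRT85 at -0.58 ± 0.46 and CYP1B1 at -0.15 ± 0.19. Within series the interferon gamma score difference was 1.27 in series 0 and 0.72 in series 2, and that of the T cell score 1.03 and 0.25. Series 0 alone gave 29 called genes, series 2 alone 0 and limma-voom 1, while DESeq2 gave 55 and no filter on low counts 76 (30 higher and 46 lower). The FFA with LPP fold change differed between the 2 series past the threshold for 0 genes (edgeR, smallest adjusted p = 0.901, 1212 unadjusted). The series themselves differed in 3864 of 23343 genes, with disease in the model.

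**Figure D2:**
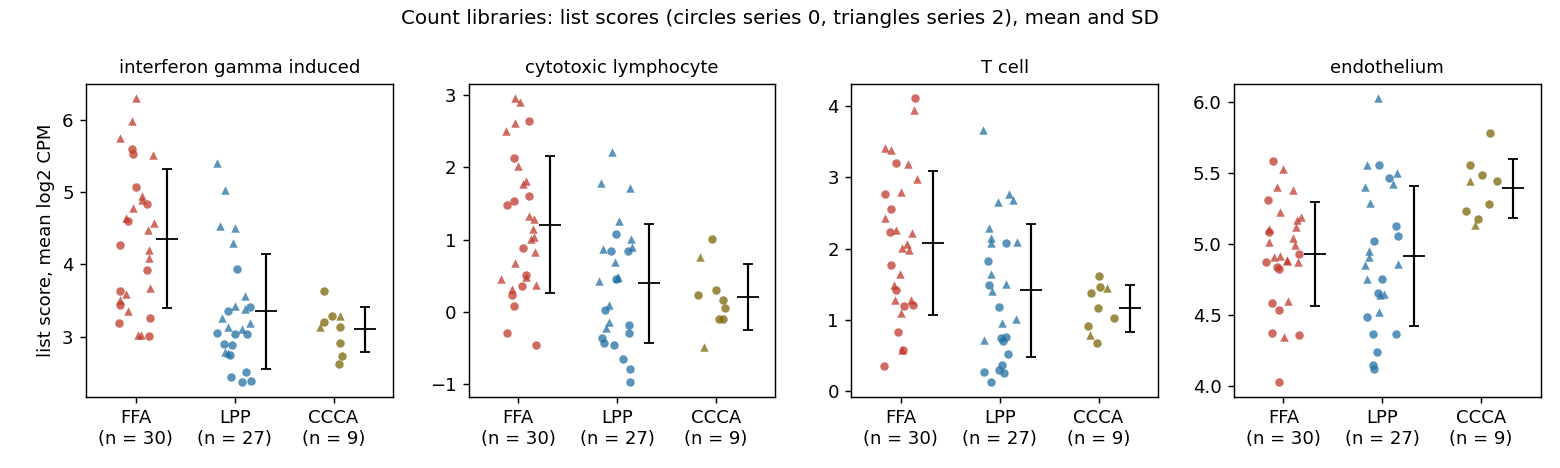
Mean log2 CPM of the interferon gamma induced, cytotoxic lymphocyte, T cell and endothelium lists in the 66 count libraries of FFA (n = 30), LPP (n = 27) and CCCA (n = 9). Circles are libraries of series 0, triangles those of series 2, and bars show the mean ± SD. Interferon gamma scores averaged 4.35 ± 0.96 in FFA, 3.35 ± 0.79 in LPP and 3.10 ± 0.31 in CCCA, and endothelium scores 4.93 ± 0.37, 4.91 ± 0.49 and 5.39 ± 0.21.

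CCCA was compared with FFA to ask which transcripts differ between the 2 diseases. In CCCA (n = 9), 7 of 18 interferon gamma induced genes were lower than in FFA (n = 30), and 4 of 12 endothelial genes were higher. Of 18 interferon gamma induced genes, 7 fell, and 14 adjusted over the list alone, with a median log2 fold change of -0.90 (adjusted p = 0.474 with an estimated correlation). Lists that can mark library quality had medians above 0 as well. Ribosomal protein genes had 0.14 (camera adjusted p = 0.00419, adjusted p = 0.731 with an estimated correlation), with 1 call in 20, RPL13, and 2 adjusted over the list alone. Mitochondrially encoded genes had 0.22 (camera adjusted p = 0.00345, adjusted p = 0.731 with an estimated correlation), with 0 calls in 13, and 1 adjusted over the list alone. Within series 0 and 2 these medians were 0.21 and -0.19, and 0.24 and -0.01. CXCL9 (-4.61 ± 1.02, 1.52 ± 1.11 against 50.1 ± 68.6 CPM) fell 24.4-fold, with CXCL10 (-4.49 ± 1.02, 0.522 ± 0.402 against 19.8 ± 27.7 CPM), CXCL11 (-3.52 ± 0.89), GBP1 (-1.24 ± 0.31) and GBP5 (-1.71 ± 0.49). The T cell checkpoint gene CTLA4 (-1.77 ± 0.42), the dendritic cell gene LAMP3 (-0.86 ± 0.22) and KLHDC7B (-2.11 ± 0.54) fell as well. T cell genes passed 0 of 15 over all genes and 12 adjusted over the list alone (median -1.03, adjusted p = 0.731 with an estimated correlation), with CD5 at -0.95 ± 0.30 and ICOS at -1.75 ± 0.58. Cytotoxic genes passed 0 of 17 and 10 adjusted over the list alone (median -0.93, adjusted p = 0.700 with an estimated correlation), with CD8A at -1.47 ± 0.42 and GZMB at -1.27 ± 0.49. Of 12 endothelial genes, 4 rose, and 11 adjusted over the list alone, with a median of 0.49 (adjusted p = 0.379 with an estimated correlation). They were PECAM1 (ENSG00000261371, chromosome 17, 64319415 to 64413776, 0.62 ± 0.15, 153 ± 28.4 against 107 ± 22.96 CPM), CLDN5 (0.99 ± 0.24, 73.6 ± 16.9 against 37.7 ± 13.4 CPM), the angiopoietin receptor TEK (0.56 ± 0.15) and PLVAP (0.64 ± 0.18). Of 15 smooth muscle genes, 1 rose, TAGLN (0.76 ± 0.19), and 9 adjusted over the list alone (median 0.57, adjusted p = 0.474 with an estimated correlation). The call of TAGLN ended without CCCA replicates 1, 4, 6 or 7 (down to 0.63). Of 9 fits without 1 CCCA replicate, the call ended in 7 for PLVAP, 6 for TEK, 2 for CLDN5 and 1 for PECAM1. Within series 0 and 2, the endothelial medians were 0.52 and 0.18 and the smooth muscle medians 0.72 and 0.20. TNNT1 (0.80 ± 0.21) and the aldehyde dehydrogenase ALDH3A1 (1.03 ± 0.26) rose, and the epidermal keratins KRT1 (0.57 ± 0.17) and KRT10 (0.59 ± 0.18) had edgeR adjusted p = 0.0539 and 0.0616. TPSAB1 (0.75 ± 0.27), KIT (0.28 ± 0.21), COL1A1 (0.59 ± 0.35), PPARG (-0.12 ± 0.22), HMGCS1 (-0.65 ± 0.40), KRT15 (0.27 ± 0.17), KRT85 (-0.58 ± 0.72) and CYP1B1 (-0.33 ± 0.29) did not pass. Pseudogenes also rose, and their source is uncertain, since near-identical copies share reads. Among them were MTND1P23 (4.72 ± 0.99), MTCO1P12 (3.56 ± 0.43), RPL29P11 (3.53 ± 0.54), RPL10P9 (3.26 ± 0.68) and RPL10P6 (2.93 ± 0.58). edgeR called 305 genes higher and 121 lower of 23343, and 3909 passed unadjusted. The count fell to 160, 171, 194, 241, 173, 91 and 272 without CCCA replicates 1, 2, 4, 5, 6, 7 and 9 in turn, to 193 without a filter, 115 in series 0 and 3 in series 2, and rose to 721 with DESeq2 (419 higher and 302 lower) and 1037 without the series covariate. Of 20 named calls 6 held in all 9 such fits, CXCL9, CXCL10, CTLA4, MTCO1P12, RPL10P6 and RPL10P9, while RPL29P11 went to -0.47 without replicate 6 and below 0 with DESeq2, and MTND1P23 to 1.84 without replicate 3.

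CCCA was compared with LPP for the same question. In CCCA (n = 9), 2 of 12 endothelial and 1 of 15 smooth muscle genes were higher than in LPP (n = 27), and proliferation and hair shaft genes had negative medians. Interferon gamma induced, cytotoxic and T cell genes, with larger negative medians against FFA, had medians of -0.10, -0.14 and -0.29 against LPP. Of their 18, 17 and 15 genes, 0 passed over all genes or adjusted over the list alone (adjusted p = 0.911 with an estimated correlation for each list). Of 12 endothelial genes, 2 rose, PLVAP (0.74 ± 0.18, 93.9 ± 19.7 against 60.1 ± 21.9 CPM) and CLDN5 (0.89 ± 0.24), and 10 adjusted over the list alone, with PECAM1 at 0.51 ± 0.15 (median 0.47, adjusted p = 0.439 with an estimated correlation). Of 15 smooth muscle genes, 1 rose, TAGLN (0.68 ± 0.19, 306 ± 109.7 against 191 ± 68.99 CPM), and 9 adjusted over the list alone (median 0.60, adjusted p = 0.439 with an estimated correlation). The call of TAGLN ended without any 1 of CCCA replicates 1 to 8 (down to 0.55). Of 9 fits without 1 CCCA replicate, the call ended in 7 for CLDN5 and 3 for PLVAP. Within series 0 and 2, the endothelial medians were 0.58 and 0.15 and the smooth muscle medians 0.61 and 0.21. Of the lists that can mark library quality, ribosomal protein genes had a median of 0.17 (camera adjusted p = 0.00505, adjusted p = 0.911 with an estimated correlation), with 1 call in 20, RPL13, and 3 adjusted over the list alone. Mitochondrially encoded genes had 0.25 (camera adjusted p = 0.000193, adjusted p = 0.854 with an estimated correlation), with 1 call in 13, MT-ND6, and 1 adjusted over the list alone. Within series 0 and 2 these medians were 0.27 and -0.24, and 0.35 and -0.05. The TGF-beta list gave 2 calls in 14, TGFB1 (0.46 ± 0.12) and TGFBI (0.76 ± 0.20), and 2 adjusted over the list alone. The cornified envelope gene LOR (0.92 ± 0.25, 1384 ± 778 against 722 ± 285 CPM) and KRT10 (0.63 ± 0.18) rose among 18 epidermal differentiation genes, and 3 adjusted over the list alone (adjusted p = 0.854 with an estimated correlation). The immediate early and heat shock list had a median of 0.42 (-0.33 in series 0 and 1.52 in series 2) with 2 calls in 15, HSPA1A and HSPA1B, and 2 adjusted over the list alone. The heat shock gene HSPA1A (0.47 ± 0.10), ALDH3A1 (0.97 ± 0.26) and TNNT1 (0.81 ± 0.21) rose as well. Of 16 proliferation genes, 0 passed over all genes and 7 fell adjusted over the list alone (median -0.39, adjusted p = 0.854 with an estimated correlation). The hair shaft keratin list had a median of -0.96 with 0 calls in 15, and 0 adjusted over the list alone (adjusted p = 0.911 with an estimated correlation), with KRT85 at -1.16 ± 0.72 (1049 ± 531 against 2103 ± 1874 CPM). In this list 1 CCCA library stood below the other 8, with a score of 3.82 against 6.92 for the nearest. CXCL9 (-1.96 ± 0.95), CXCL10 (-2.13 ± 0.99), GZMB (-0.14 ± 0.48), CD8A (-0.38 ± 0.41), TPSAB1 (0.70 ± 0.27), KIT (0.28 ± 0.22), COL1A1 (0.30 ± 0.35), PPARG (-0.10 ± 0.22), HMGCS1 (-0.68 ± 0.41), KRT15 (0.33 ± 0.17) and CYP1B1 (-0.47 ± 0.29) did not pass. Among the largest calls, MTND1P23 (4.33 ± 1.001), RPL29P11 (3.65 ± 0.52), SORD2P (3.01 ± 0.42), MTCO1P12 (2.498 ± 0.46) and RPL10P6 (2.19 ± 0.60) were higher pseudogenes of uncertain source. BEST4 (-1.40 ± 0.32), LSMEM1 (-1.21 ± 0.34), the pseudogene HERC2P2 (-1.11 ± 0.24), LINC01176 (-1.08 ± 0.24) and ZNF788 (-1.06 ± 0.17) were lower. edgeR called 299 genes higher and 71 lower of 23343, and 3771 passed unadjusted. The count fell to 107, 140, 127, 167, 193, 84 and 200 without CCCA replicates 1, 2, 4, 5, 6, 7 and 9 in turn, to 127 without a filter, 152 in series 0 and 0 in series 2, and rose to 607 with DESeq2 (360 higher and 247 lower) and 675 without the series covariate. Of 20 named calls 7 held in all 9 such fits, BEST4, HERC2P2, HSPA1A, LINC01176, MTCO1P12, SORD2P and ZNF788, while RPL29P11 went to -0.39 without replicate 6 and below 0 with DESeq2, and MTND1P23 to 1.43 without replicate 3.

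No control was a count library, so CCCA was set against NC only indirectly, by adding 2 fold changes, with no p-value. Through FFA and through LPP, sebaceous gland genes had medians of -3.65 and -3.82, cholesterol synthesis genes -1.45 and -1.44 and mast cell genes 1.89 and 1.59. Fibrillar matrix genes had medians of 1.13 and 1.07, and endothelial genes 0.93 and 1.04, with 12 of 12 endothelial genes more than 2 standard errors above 0 by both routes. These standard errors leave out any difference between the FPKM and count libraries of a disease. Both routes use the same CCCA and NC libraries, so they are not independent, and a batch that follows the titles would enter both. T cell genes stood at -0.50 and 0.55 and interferon gamma induced genes at -0.10 and 0.61, so their sign depended on the route. Across genes, which are not independent replicates, the values through FFA correlated with the fold changes of the authors' CCCA table with Pearson r = 0.473. The FFA with NC fold changes of the FPKM libraries correlated with the authors' FFA table at Pearson r = 0.496. The first of these correlations therefore need not be particular to CCCA.

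The authors' 3 deposited comparison tables, FFA, LPP and CCCA against control, were read for what they share. In them, sebaceous gland genes had median log2 fold changes of -2.35 in FFA, -2.45 in LPP and -3.26 in CCCA, cholesterol synthesis genes -1.20, -1.01 and -1.25, and mast cell genes 1.48, 1.47 and 1.19. Endothelial genes had medians of 0.59, 0.74 and 0.90 and red blood cell genes 4.63, 4.88 and 5.57. Fibrillar matrix genes had medians of 0.45, 0.55 and 0.14, the last of them below the indirect CCCA values of 1.13 and 1.07. Immediate early genes had medians of 2.25, 2.09 and 1.29 there, against -0.33 for FFA and -0.29 for LPP in the fits of the FPKM libraries. Cut-offs chosen for this summary were an adjusted p, as the authors gave it, under 0.05 and an absolute log2 fold change of at least 1. With them the FFA table held 5356 higher and 1074 lower genes, the one for LPP 5424 and 1118, and the one for CCCA 4279 and 1710. All 3 tables shared 3363 higher and 803 lower genes, where independent lists would share 207.3 and 3.4. Part of the excess may come from the controls that the tables share. Of 2562 genes called in the authors' FFA table and tested in the FPKM libraries, 83.3% had the same direction there, 53.4% also passed and 145 passed in the opposite direction. Of 2595 such genes in the LPP table, 79.2% had the same direction, 38.8% also passed and 100 passed in the opposite direction.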

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

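The tests of a batch along the title ranges, of lesional status, of other counts behind the authors' tables and of regroupings in the count libraries were chosen after the results were seen.

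Of 189 groups of values tested for a library apart from its group by Dixon's ratio, 10 passed (5.29%), and chance passes about 1 in 20. The groups of values share libraries and so are not independent. Passes in FFA were 0 of 36 list scores and 1 of 70 genes. In FFA, ZBED6 had 1 library below the other 5 (ratio 0.712, log2(FPKM + 1) of 1.15 against 2.96 for the nearest). In CCCA, 6 of 37 list scores and 3 of 44 genes passed. CCCA libraries of both series were taken as 1 group, so a library apart from it may mark its series. The hair shaft keratin (ratio 0.669, mean log2 CPM of 3.82 against 6.92 for the nearest), inner root sheath (0.703, 3.85 against 6.85) and keratin-associated protein scores (0.629, 2.16 against 5.78) were lowest in 1 and the same CCCA library, and KRT85 had 1 low library too (0.703, 5.58 against 9.18). The fibrillar matrix score had 1 high library (0.599, 7.67 against 7.14), the TGF-beta response score 1 low one (0.584, 4.96 against 5.37) and the dendritic and Langerhans cell score 1 low one (0.510, 1.26 against 2.40). RPL29P11 was high in 1 library (0.910, 6.96 against 1.03) and RPL10P9 low in 1 (0.707, 2.28 against 5.71).

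Many genes differed between patients and controls in the FPKM libraries, and regrouping the samples argued against chance for both diseases. In 1 of 100 splits of the FFA and NC libraries, the real one with 6794 genes, as many were called, and the highest other split called 11. For LPP and NC it was also 1 of 100, with 4699 genes against 1595. A share of 1 in 100 is the smallest these splits can give, so chance is made unlikely and not excluded. Which libraries the split with 1595 genes put together was not examined, so the cause of its count is not known. A gene length bias of single libraries is argued against, since 92.508% of the FFA calls kept their direction and call after a length trend was removed from each library. A batch that follows the title ranges cannot be told apart from disease, because 0 libraries had a title number within the other group's range, so a biological difference between patients and controls stays open and untested against it.

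Within this pattern, a lower content of sebaceous glands may carry the fall of the cholesterol genes, which share no member with the sebaceous list. Among the 12 controls, the cholesterol score followed the sebaceous score (slope 0.597, Pearson r = 0.962, Spearman rho = 0.979, permutation p = 1e-05 for each, the smallest possible, adjusted p = 1e-05 over 2 relations), and r was 0.977 without the 2 farthest libraries. In the 66 count libraries, within disease and series, the slope was 0.350 (r = 0.918, rho = 0.949, permutation p = 1e-05 for each, r = 0.911 without the 2 farthest). These slopes and the difference of -2.87 in sebaceous score would give 143.2% and 83.815% of the FFA minus NC difference of -1.20 in cholesterol score. The second slope is of mean log2 CPM but was applied to a difference in mean log2(FPKM + 1), so its share is approximate. The cholesterol difference left over was 0.52 with the first slope and -0.19 with the second, of opposite sign. A lower cholesterol synthesis in the same cells stays open, since no test separated cell content from expression per cell.

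Interferon gamma and cytotoxic genes were higher in FFA than in LPP in the count libraries. In 1 of 100 splits within series, the real one with 25 genes, as many were called, and the highest other split called 11. This argues against chance for the number of calls but does not exclude it, since 1 of 100 is the smallest share possible. The number of splits in the count libraries, for this and both CCCA comparisons, was raised after the values of a smaller first draw were seen. A difference between the title series is argued against by the smaller within-series median of the interferon gamma list, 0.56349, and a few FFA libraries by a difference of group medians that was 123.18% of the difference of means. A larger T cell infiltrate in the FFA biopsies could account for part, since 38.992% of the list's median log2 fold change was left with the T cell score as a covariate. The median of the cytotoxic list went from 0.88 to 0.19 with the same covariate. A mix of lesional and non-lesional biopsies cannot be told apart from disease, as 0 libraries had a label for it, and a difference between the diseases at equal infiltrate stays open.

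At a log2 fold change of at least 1, the authors' tables called more genes, and partly other genes, than the comparison within the FPKM libraries. Counts other than those in the deposited columns may lie behind them, since for 48.873% of 11045 genes their mean normalized count, scaled by the median ratio, lay outside the range of all 87 libraries, 3514 below and 1884 above. Differences between the count and FPKM libraries cannot be told apart from this, as the authors' excess over the FPKM fold change correlated with that difference at Pearson r = 0.22139 across genes (0.262 for LPP), between the values set beforehand for and against. Spearman rho was 0.363 (0.388 for LPP), above the value set beforehand for Pearson r. No biological explanation was tested for this pattern.

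For the other comparisons, regroupings of the samples gave values that bear on the gene counts. In FFA with LPP of the FPKM set the real count was 0, which each of the 84 splits had to reach, so these splits decide nothing about chance. The highest other called 394, and the cause of that count was not tested. For CCCA with FFA, 2 of 100 splits called as many as the real 426 genes and the highest other called 1585. For CCCA with LPP, 2 of 100 called as many as the real 370 and the highest other 764. The real split was counted among the 2 in both, a share under 0.05 that argues against chance. It does not exclude chance, since 1 other split in each comparison called more genes than the real one. Why the 1 other split of CCCA and FFA called 1585 genes, several times the real count, was not tested.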

How the results depend on the processing

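Alternatives marked in the methods as chosen after seeing the data were so chosen, and the cause of a change was not tested unless fewer samples or genes explain it. Of 107 alternative values of main results, 58 stayed within 1.5 times of the reported value and 49 moved. Calls of FFA with NC ran from 5658 to 7161 over 16 alternatives and of LPP with NC from 2902 to 5184 over 13. Of 3303 alternative values of named genes, 2870 kept direction and side of the threshold, 333 fell short of it, 28 newly passed, 69 changed sign and 3 moved in the indirect comparison. Changes of sign were 0 of 1036 in FFA with NC and 0 of 676 in LPP with NC.

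FFA with LPP in the FPKM libraries gave 2 calls with limma on log2(FPKM + 1), 5 without its filter, 3 with quantile normalization and 16 with DESeq2. Leaving out 1 LPP replicate gave 0 to 24 (24 without replicate 3) and 1 FFA replicate 0 to 1, and for LPP with NC 2902 to 4147. In the count libraries FFA with LPP gave 55 calls with DESeq2, 76 without a filter, 0 in series 2, 1 with limma-voom and 8 with the T cell score as a covariate. CCCA with FFA gave 721, 193, 1037, 115 and 3 with DESeq2, without a filter, without the series covariate, in series 0 and in series 2, and CCCA with LPP 607, 127, 675, 152 and 0. Leaving out 1 CCCA replicate gave 91 to 585 and 84 to 449. List tests with an estimated correlation gave 0 calls instead of 14 (FFA with NC), 0 instead of 17 (LPP with NC), 0 instead of 1 (FFA with LPP), 3 instead of 18 (FFA with LPP, count libraries), 0 instead of 15 (CCCA with FFA) and 0 instead of 10 (CCCA with LPP). Exact permutation of scores gave 10 in LPP with NC and 0 in FFA with LPP, where its 84 regroupings could not call a lone list, so that 0 cannot weigh against 1. Quantile normalization gave 2 there, and permutation within series 3 in the count libraries. The authors' tables shared 4166 genes, 8580 by adjusted p alone and 1243 at the stricter thresholds.

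In FFA with LPP of the FPKM libraries, CD8A turned to -0.0135 with limma on log2(FPKM + 1), with and without a filter, -0.132 with a pseudocount of 0.1, -0.0252 on TPM and -0.0605 with quantile normalization. In the same order COL1A1 turned to 0.0399 (both), 0.0407, 0.0816 and 0.104, HMGCS1 to -0.0706 (both), -0.0739, -0.0314 and -0.066, and CYP1B1 to 0.00211 (both), 0.00134 and 0.0422, with 0.000701 in edgeR without a filter. KIT turned to 0.0341 on TPM. Over fits without 1 replicate, CD8A ran from -0.353 to 0.744, PPARG from -0.119 to 0.597, KRT85 from -0.291 to 0.743, TPSAB1 from -0.292 to 0.412, COL1A1 from -0.475 to 0.218, CYP1B1 from -0.109 to 0.0872, KIT from -0.211 to 0.343 and HMGCS1 from -0.302 to 0.477, and in the CCCA comparisons RPL29P11 from -0.467 to 3.77 (FFA) and -0.391 to 3.87 (LPP) and GZMB from -0.486 to 0.0561 (LPP). In FFA with LPP of the count libraries, KIT turned to -0.00292 (DESeq2 size factors), -0.00298 (DESeq2), -0.275 (series 2), -0.0136 (limma-voom) and -0.0563 (T cell covariate). There KRT15 turned to -6.59e-05 without the covariate and -0.108 in series 0, TPSAB1 to 0.308 in series 0, HMGCS1 to 0.371 in series 0 and 0.286 with the T cell covariate, PPARG to -0.0444 and CYP1B1 to 0.00595 in series 2. In CCCA with FFA, RPL29P11 turned to -0.468 with DESeq2 and -0.33 in series 2, and series 2 gave -0.304 for TPSAB1 and 0.351 for PPARG. In CCCA with LPP, RPL29P11 turned to -0.399 with DESeq2, GZMB to 0.353 in series 0, and series 2 gave -0.653 for TPSAB1 and 0.307 for PPARG. The depth of 11736004 counts or more per library was not varied.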

Other observations

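Other lists were counted between patients and NC in the FPKM libraries. Counts over all genes tested are followed in brackets by those adjusted over the list alone. Antigen presentation (15 genes) gave 9 higher and 0 lower [10 and 0] in FFA, adjusted p = 0.842 with an estimated correlation, and 4 higher and 0 lower [4 and 0] in LPP. TGF-beta response (14 genes) gave 5 higher and 2 lower [8 and 2] in FFA, and 4 higher and 0 lower [4 and 0] in LPP. Immediate early and heat shock (15 genes) gave 0 higher and 7 lower [0 and 7] in FFA, adjusted p = 0.541 with an estimated correlation, and 1 higher and 4 lower [1 and 4] in LPP, adjusted p = 0.653 with an estimated correlation. Eccrine gland (11 genes) gave 0 higher and 4 lower [0 and 4] in FFA, and 0 higher and 4 lower [0 and 4] in LPP, adjusted p = 0.708 with an estimated correlation. Inner root sheath (10 genes) gave 0 higher and 3 lower [0 and 3] in FFA, and 0 higher and 2 lower [0 and 0] in LPP, adjusted p = 0.749 with an estimated correlation. Keratin-associated protein (13 genes) gave 2 higher and 0 lower [1 and 0] in FFA, and 0 higher and 0 lower [0 and 0] in LPP. Dendritic and Langerhans cell (12 genes) gave 4 higher and 0 lower [4 and 0] in FFA, and 2 higher and 0 lower [0 and 0] in LPP. Lymphoid organisation (7 genes) gave 2 higher and 0 lower [2 and 0] in FFA, and 2 higher and 0 lower [3 and 0] in LPP. B and plasma cell (14 genes) gave 2 higher and 1 lower [2 and 1] in FFA, and 2 higher and 0 lower [2 and 0] in LPP. Th2 chemokine and cytokine (10 genes) gave 1 higher and 3 lower [1 and 3] in FFA, and 2 higher and 2 lower [2 and 2] in LPP. Melanocyte (11 genes) gave 0 higher and 0 lower [0 and 0] in FFA, and 0 higher and 0 lower [0 and 0] in LPP. Proliferation (16 genes) gave 0 higher and 1 lower [0 and 0] in FFA, and 0 higher and 0 lower [0 and 0] in LPP. Epidermal differentiation (18 genes) gave 1 higher and 3 lower [0 and 0] in FFA, and 1 higher and 1 lower [1 and 0] in LPP. Smooth muscle (15 genes) gave 1 higher and 1 lower [0 and 0] in FFA, and 0 higher and 0 lower [0 and 0] in LPP. Skeletal muscle (12 genes) gave 2 higher and 2 lower [2 and 2] in FFA, and 3 higher and 2 lower [3 and 2] in LPP. Schwann cell (8 genes) gave 2 higher and 1 lower [2 and 1] in FFA, and 2 higher and 0 lower [2 and 0] in LPP. Aryl hydrocarbon receptor (6 genes) gave 0 higher and 2 lower [0 and 3] in FFA, and 0 higher and 1 lower [0 and 2] in LPP. Non-polyadenylated RNA (8 genes) gave 3 higher and 1 lower [4 and 1] in FFA, and 2 higher and 1 lower [3 and 1] in LPP. Ribosomal protein (20 genes) gave 3 higher and 0 lower [0 and 0] in FFA, and 2 higher and 0 lower [0 and 0] in LPP. In LPP, macrophage genes gave 3 higher and 0 lower [2 and 0] of 15, adjusted p = 0.708 with an estimated correlation, and T cell genes 2 higher and 0 lower [0 and 0] of 15. In FFA, epidermal stress genes gave 0 higher and 2 lower [0 and 0] of 21. Red blood cell scores were above every control in 4 of 6 FFA and 3 of 3 LPP libraries.

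In the count libraries, other lists with an adjusted camera p under 0.05 at the preset correlation lost it with an estimated correlation. Where no count is given, 0 members passed either way. In FFA against LPP, the medians were type I interferon induced genes 0.35 (0 higher and 0 lower [4 and 0], adjusted p = 0.170 with an estimated correlation), lymphoid organisation genes 0.52 (0 higher and 0 lower [1 and 0], adjusted p = 0.287 with an estimated correlation), macrophage genes 0.18 (adjusted p = 0.429 with an estimated correlation) and dendritic and Langerhans cell genes 0.40 (0 higher and 0 lower [3 and 0], adjusted p = 0.105 with an estimated correlation). Next to these stood fibrillar matrix genes -0.21 (adjusted p = 0.332 with an estimated correlation), hair shaft keratin genes -0.52 (adjusted p = 0.502 with an estimated correlation), keratin-associated protein genes -0.47 (adjusted p = 0.630 with an estimated correlation) and inner root sheath genes -0.48 (adjusted p = 0.551 with an estimated correlation). Then came melanocyte genes -0.27 (adjusted p = 0.396 with an estimated correlation), epidermal stress and antimicrobial genes -0.50 (adjusted p = 0.287 with an estimated correlation), proliferation genes -0.14 (adjusted p = 0.551 with an estimated correlation) and eccrine gland genes 0.09 (adjusted p = 0.505 with an estimated correlation). There were also Schwann cell genes 0.29 (0 higher and 0 lower [1 and 0], adjusted p = 0.105 with an estimated correlation). Within series 0 and 2, the hair shaft keratin score differed by -1.63 and 0.39. In CCCA against FFA, they were type I interferon induced genes -0.37 (adjusted p = 0.731 with an estimated correlation), antigen presentation genes -0.36 (adjusted p = 0.731 with an estimated correlation), dendritic and Langerhans cell genes -0.45 (0 higher and 1 lower [0 and 1], adjusted p = 0.731 with an estimated correlation) and fibrillar matrix genes 0.18 (adjusted p = 0.731 with an estimated correlation). Next to these stood melanocyte genes 0.16 (1 higher and 0 lower [1 and 0], adjusted p = 0.731 with an estimated correlation), epidermal differentiation genes 0.19 (0 higher and 0 lower [4 and 0], adjusted p = 0.731 with an estimated correlation), epidermal stress and antimicrobial genes 0.06 (adjusted p = 0.731 with an estimated correlation) and proliferation genes -0.24 (adjusted p = 0.731 with an estimated correlation). In CCCA against LPP, they were keratin-associated protein genes -1.27 (adjusted p = 0.911 with an estimated correlation), eccrine gland genes 0.41 (adjusted p = 0.854 with an estimated correlation) and Schwann cell genes 0.36 (adjusted p = 0.854 with an estimated correlation). Without such a camera call, sebaceous gland genes had medians of -0.88 in CCCA against FFA and -0.76 against LPP, with 0 members past the threshold either way.

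In a principal component analysis of the FPKM libraries, the first component held 35.99% of the variance and the second 11.5%, and every patient library lay on 1 side of 0 on the first with every control on the other. Between the series of count libraries, 3864 of 23343 genes differed, 1597 higher and 2267 lower in series 2, with disease in the model. The median, mean and test of a list differed in sign for 17 list comparisons, none of them with a call from camera over the lists. Through FFA 4 of the 12 fixed genes were above 0 in CCCA against NC, and through LPP 6 were.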
